A study of Paralichthys olivaceus with 22 samples.

How the data were processed

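Kidney RNA of Paralichthys olivaceus was labelled with Cy3 and hybridised to a custom Agilent design, 1 sample per array. The deposited scanner files give spot intensity values, which per the file headers were read with Feature Extraction 10.7.3.1 and background-subtracted and detrended within each array. The submitters' processing notes name Agilent Feature Extraction 9.5.3.1, and the difference is not explained in the sources used here. The authors also deposited a table of log2 values. Set against the scanner values, it holds log2 processed signal minus each array's 75th percentile and minus the per-probe median of the PBS arrays of the same time, and 100.0% of its values lay within 0.1 and 53.3% within 0.01 of that reconstruction. Its column medians ranged from -0.274 to 0.0274. It was used as an alternative, and does not allow the comparison of PBS over time because it is centred within each time.

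Each array holds 15197 spots, of which 536 are control spots and 14661 carry 14481 probes, 20 of them with 10 spots. The median SD of the 10 spots within an array was 0.076 on the log2 scale. No spot was saturated. Spots flagged as non-uniform or population outliers were left out, which left 94 missing values among the tested probes. The log2 processed signal minus the array's 75th percentile was averaged over spots of a probe. Probes well above background on at least 3 of the 22 arrays were tested, which left 11066, and 6779 were well above background on all arrays. The 75th percentile of the signal ranged from 209 to 470 between arrays.

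A model with 1 mean for each of the 6 groups was fitted to all arrays with limma 3.58.1 in R 4.3.3, with 16 residual degrees of freedom. The 10 contrasts were tested with lmFit and eBayes, and probes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. Groups, contrasts, the rule for named features and the alternatives, apart from the 2 named below, were fixed before the data were examined. Tested on data simulated for E. tarda FKC against PBS at 6 h with 11066 probes and 200 changed, the fit recovered 36% of 2-fold changes and 80% of 4-fold changes. The expected recovery from the power of the test was 38.2% and 79.4%, and 7 of 123 calls were false. A floor of recovery set earlier for this test was not met by the 2-fold changes and was replaced by that comparison with the expected power. Sparse changes of 2-fold are thus often missed at this number of arrays.

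None of the names in the files matched the table of RefSeq genes for assembly ASM2471397v2, so 0 of the 29 gene lists fixed beforehand had a matched name and no list, marker or pathway was tested. The rule for named genes then allowed 2 probes that rose and 2 that fell. They are the largest changes over the 4 comparisons with PBS among probes that were called, had no overlap between the groups and were well above background on every array of both groups.

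The slide and the row on it were read from the file headers. The scan time in the headers is the same for the arrays of a slide, so scan and slide are 1 batch. A slide term cannot be added to the group means, because each group lies on 1 slide, and a comparison within a slide holds no difference between slides, though its groups lie in different rows. Alternatives were normexp background correction with an offset of 50 and quantile normalization, quantile normalization alone, scaling to the median, the authors' values, no filter, a filter for all arrays, a fit of the compared groups alone, a replicate block, eBayes with trend and robust, array weights, a 2-fold minimum and leaving out each array. The plan named mean spot signals for normexp, and median spot signals took their place after the columns of the files had been seen. Keeping outlier spots was also added after seeing the data. Arrays shared between comparisons were treated by 100 simulations of unchanged groups and by 6 splits of the PBS arrays. Ratios of changes over called probes were also taken on arrays left out of the selection, with 2 arrays of each group used to select and the ratio of summed changes, signed by the selection, computed on the rest.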

Results

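Kidney RNA of Japanese flounder was measured on 22 1-colour arrays after the fish received an FKC preparation of Edwardsiella tarda, an FKC preparation of Streptococcus iniae, or PBS as the control. FKC is the term the labels use for both bacterial preparations. Kidneys were taken at 6 h and at 12 h. Each preparation had 3 arrays at 6 h and 4 arrays at 12 h, and PBS had 4 arrays at each time. The labels number the samples of a group and do not say whether each came from a separate fish, so the p-values measure the spread between these samples, which may be partly technical. Between 8084 and 10666 of the 14481 probes were well above background on an array, and 11066 probes were tested. The number of arrays limits the precision. The probes carry contig or GenBank names and the files pair them with no gene names, so the results are given as groups of probes, and by ID for 2 probes that rose and 2 that fell.

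The arrays separated by treatment along the first principal component, which held 30.3% of the variance over 10979 probes. All PBS arrays lay on a slide without FKC arrays, so their separation from the FKC arrays does not tell treatment from slide. The PBS arrays lay between 33.7 and 45.5 on this component at both times. The S. iniae arrays lay between 21.4 and 25.05 at 6 h and between -15.6 and 3.04 at 12 h. The E. tarda arrays lay between -40.7 and -27.2 at 6 h and between -72.9 and -65.6 at 12 h. On the second component, with 14.5% of the variance, the FKC arrays of 6 h, on 1 slide, lay at -16.2 or less. Those of 12 h, on another slide, lay at 0.99 or more. The PBS arrays, all on 1 slide, lay between -15.5 and 1.68 at 6 h and between 9.52 and 30.3 at 12 h. Arrays of 1 group correlated at a median of 0.963 across probes, against 0.934 for arrays of different groups, and no pair of arrays held the same values.

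**Figure D1:**
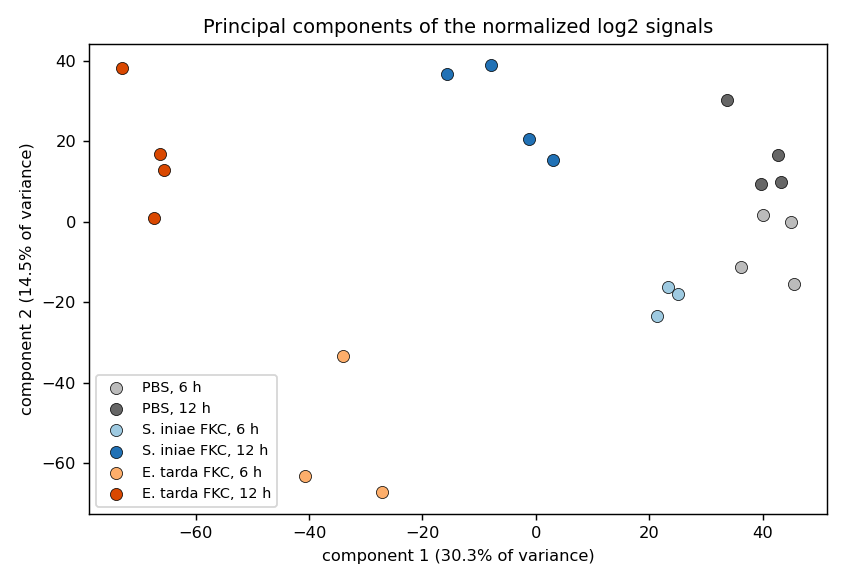
Each point is 1 of the 22 arrays, placed by its first (x axis) and second (y axis) principal component score, with no unit, of the normalized log2 signals, and coloured by group. The PBS arrays lie at 33.7 or more on the first component and the E. tarda arrays at -27.2 or less, with the S. iniae arrays between them. The PBS arrays were on a slide without FKC arrays.

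The first comparison asked which transcripts differed after E. tarda FKC. At 6 h, 1557 probes rose and 1554 fell against PBS, which was 28.1% of the probes tested. Without E. tarda replicate 2 the count of 3111 was 1994, and without any other single array it moved by less than 1.5 times. Of the 3111, 1017 rose and 724 fell by at least 2-fold, and 124 rose and 10 fell by at least 8-fold. At 12 h, 1726 probes rose and 2250 fell, which was 35.9% of the probes tested, and 147 rose and 56 fell by at least 8-fold. The balance of directions rested on the processing. At 12 h the median of all tested probes lay at -0.12 on the log2 scale, and with arrays scaled to their median 2006 probes rose and 1794 fell. At 6 h that scaling gave 1386 higher and 1756 lower, and probes well above background on all arrays gave 990 higher and 1395 lower. The 2 times shared 857 probes that rose and 713 that fell, where independent lists would share 243 and 316. The PBS arrays of both times lay on 1 slide without FKC arrays. An offset of that slide would enter both lists and raise this overlap. In the opposite direction, 65 probes rose at 6 h and fell at 12 h, and 28 fell at 6 h and rose at 12 h. In 354 of the calls at 6 h and 689 at 12 h the probe was not well above background on any array of 1 group, so its fold is not a measured size.

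The probes with the largest rise were CUST_6587_PI426483990, of contig JFC00244_1_code, and CUST_13312_PI426483990, of contig JFC03172_1_code. The first went from -1.67 ± 0.72 (SD, n = 4) in PBS to 6.81 ± 0.22 (SD, n = 4) after E. tarda FKC at 12 h on the normalized log2 scale, a rise of 8.48 (SE 0.51, limma adjusted p = 5.53e-10) or 357-fold. At 6 h it rose by 7.39 (SE 0.55, limma adjusted p = 1.48e-08). The other rose by 8.32 (SE 0.53, limma adjusted p = 9.25e-10) at 12 h, from -1.45 ± 0.60 (SD, n = 4) to 6.87 ± 0.21 (SD, n = 4), and by 7.18 (SE 0.58) at 6 h. These 2 probes ran together across arrays, for example at 1.60 and 1.80 on S. iniae FKC at 12 h replicate 1 and 4.07 and 4.25 on replicate 3. Whether they report separate transcripts was not tested. The probes with the largest fall were CUST_7579_PI426483990, of contig JFC21892_1_code, and CUST_10058_PI426483990, of contig JFC02112_1_code. CUST_7579_PI426483990 fell by 6.10 (SE 0.38, limma adjusted p = 7.95e-10) at 12 h, from 4.33 ± 0.45 (SD, n = 4) to -1.76 ± 0.9997 (SD, n = 4), and fell by 2.10 (SE 0.41) at 6 h. CUST_10058_PI426483990 fell by 4.98 (SE 0.29, limma adjusted p = 5.53e-10) at 12 h, from 2.26 ± 0.39 (SD, n = 4) to -2.71 ± 0.49 (SD, n = 4), and fell by 2.26 (SE 0.31) at 6 h. All 4 probes were well above background on every array.

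**Figure D2:**
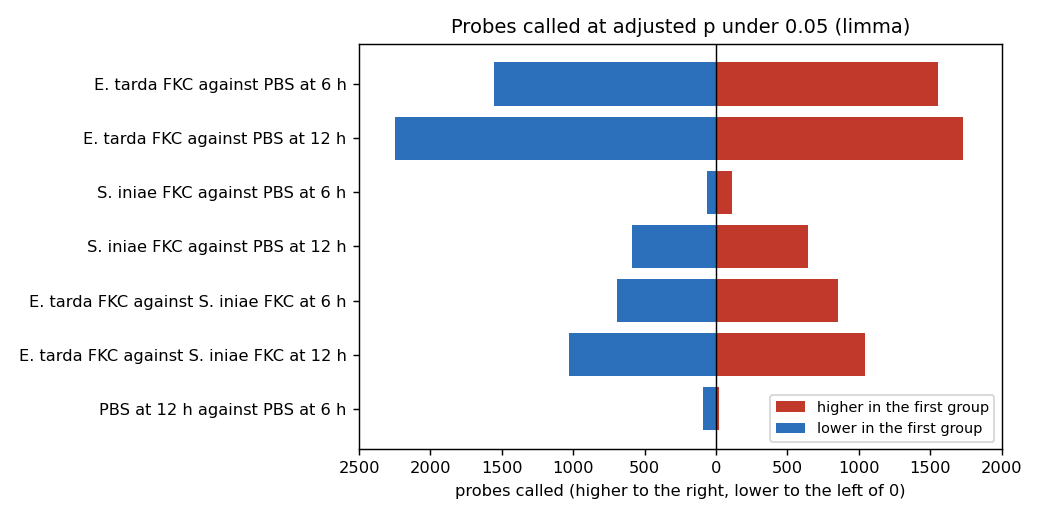
Bars give the number of probes called by limma in each comparison (x axis, probes), higher in the first-named group to the right of 0 and lower to the left. E. tarda FKC against PBS at 12 h has the longest bars, with 1726 higher and 2250 lower, and of the 7 comparisons drawn PBS over time has the fewest calls in total, with 20 and 90.

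The second comparison asked the same of S. iniae FKC. At 6 h, 115 probes rose and 61 fell against PBS, which was 1.59% of the probes tested. This count of 176 rested on single arrays and on the fit. It was 51 and 73 without S. iniae replicates 2 and 3, 88 without PBS replicate 3, 34 in the fit of the 2 groups alone, 286 with no filter, 597 with array weights and 783 with normexp and quantile normalization, and it also moved by over 1.5 times without PBS replicate 1. At 12 h, 644 rose and 589 fell, which was 11.1%, and 39 of them rose and 2 fell by at least 8-fold. This count of 1233 was 806 without S. iniae replicate 2, and 724 and 741 without PBS replicates 3 and 4. The share of called probes that rose at 12 h was 52.2%, and with arrays scaled to their median it was 71.6%, with 897 higher and 356 lower, while array weights gave 948 higher and 1008 lower and the fit of the 2 groups alone 477 higher and 574 lower. At 6 h the share was 65.3%, and 52.7% after normexp background correction and quantile normalization. With no filter it was 46.9%, with 134 higher and 152 lower. In 50 of the calls at 6 h and 186 at 12 h the probe was not well above background on any array of 1 group. The 2 times shared 61 probes that rose and 19 that fell, where independent lists would share 6.69 and 3.25. An offset of the slide that held all PBS arrays would raise this overlap too. CUST_6587_PI426483990 rose by 4.31 (SE 0.51, limma adjusted p = 2.96e-05) at 12 h and by 2.46 (SE 0.55, limma adjusted p = 0.0246) at 6 h. CUST_13312_PI426483990 rose by 4.24 (SE 0.53) at 12 h and by 2.45 (SE 0.58, limma adjusted p = 0.0351) at 6 h. Both calls at 6 h were lost without S. iniae replicate 1 (limma adjusted p of 0.079 and 0.0825), S. iniae replicate 3 (0.158 and 0.224), PBS replicate 2 (0.0576 and 0.0821) or PBS replicate 3 (0.0919 and 0.124), and in the fit of the 2 groups alone (0.147 and 0.18). CUST_7579_PI426483990 fell by 1.81 (SE 0.38, limma adjusted p = 0.00448) and CUST_10058_PI426483990 fell by 2.13 (SE 0.29, limma adjusted p = 0.000138) at 12 h. At 6 h their changes of -0.33 and -0.30 did not pass the test.

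Both comparisons with PBS lie across slides. All FKC arrays of 6 h were on slide 1, all FKC arrays of 12 h on slide 2 and all PBS arrays on slide 3, so slide and treatment against PBS cannot be told apart by a block. The E1A spike-in probes measure added control RNA and not flounder transcripts, and 7 of them were well above background on every array. From PBS to E. tarda FKC at 6 h they moved by -0.94 to 0.01 on the log2 scale, and 2 of 7 had an unadjusted limma p under 0.05. For S. iniae FKC at 6 h they moved by -0.52 to 0.15, and 1 of 7 did. At 12 h they moved by -0.31 to -0.16 for E. tarda FKC and by -0.35 to -0.23 for S. iniae FKC, and 0 of 7 had such a p in either, the smallest being 0.122 and 0.0827. The slope of the spike-in line averaged 0.968 on slide 1, 1.006 on slide 2 and 1.002 on slide 3. Within slide 1 the slopes of the 2 rows did not overlap, at 0.948 to 0.969 for E. tarda FKC and 0.971 to 0.989 for S. iniae FKC. Slide 1 was lower than slide 2 by an exact two-sided permutation test (p = 0.000666, adjusted over 9 tests 0.0015) and lower than slide 3 (exact permutation p = 0.00233, adjusted 0.0035). The root mean square that the file headers give for the fit of the multiplicative detrending averaged 0.200 on slide 1. It averaged 0.0786 on slide 2 and 0.0741 on slide 3, and slide 1 differed from each by an exact permutation test (p = 0.000333, adjusted 0.000999). The number of probes well above background was also higher on slide 1 than on slide 2 (exact permutation p = 0.000333) and slide 3 (exact permutation p = 0.002). Slide 1 holds arrays of 6 h only, and within slide 3 this number averaged 9362 on the PBS arrays of 6 h, in row 1, and 8518.5 on those of 12 h, in row 2, so it went with time or row as well as with slide. Slides 2 and 3 were not separated in slope, root mean square of the detrending fit or number of probes, with exact permutation p of 0.541, 0.276 and 0.423.

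**Figure D3:**
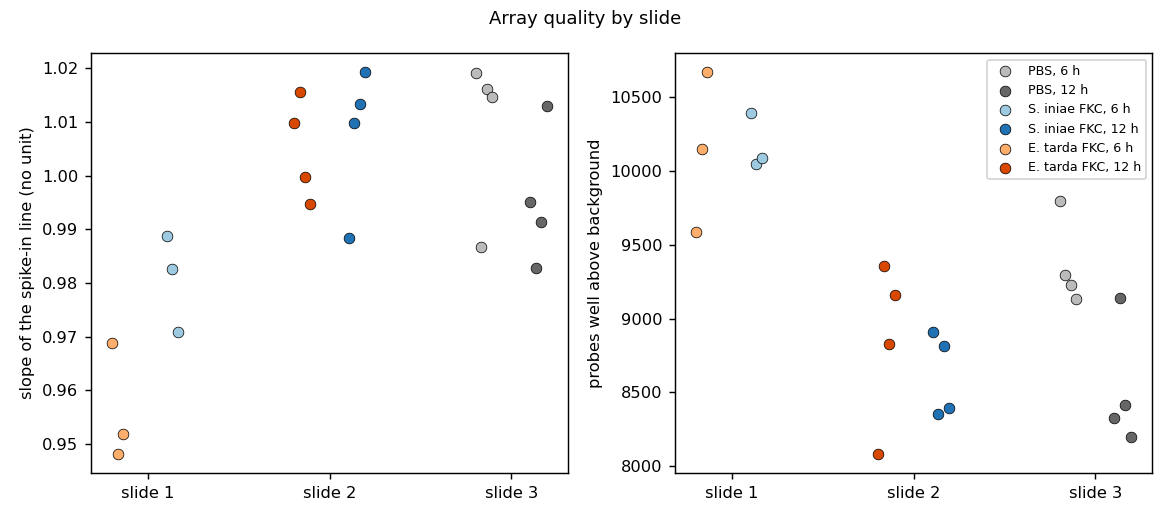
Each point is 1 array, placed by slide (x axis), with the slope of the spike-in line from the file header (left, no unit) and the number of probes well above background (right, probes) on axes that do not start at 0. The slopes of slide 1 lie between 0.948 and 0.989, and its arrays have 9583 or more probes well above background.

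The third comparison set the preparations against each other at the same time, with both on 1 slide. At 6 h, 857 probes were higher and 696 lower after E. tarda FKC than after S. iniae FKC. At 12 h, 1046 were higher and 1032 lower. The count of 1553 at 6 h was 881 without E. tarda replicate 2, and 957 and 932 without S. iniae replicates 2 and 3, and the fit of the 2 groups alone gave 689 at 6 h and 1349 at 12 h. Among calls of any size, neither time had a settled excess of 1 direction. At 6 h, scaling to the median gave 709 higher and 763 lower, quantile normalization 894 and 918, and probes well above background on all arrays 590 and 662. At 12 h, normexp with quantile normalization gave 1224 higher and 1451 lower. Larger changes in the main processing were more often higher after E. tarda FKC. Among calls of at least 2-fold, 595 were higher and 360 lower at 6 h, and 674 and 485 at 12 h. At 8-fold or more they were 65 and 3 at 6 h, and 52 and 12 at 12 h. In 139 of the 1553 calls at 6 h and 331 of the 2078 at 12 h the probe was not well above background on any array of 1 group. The fold of such a probe is not a measured size, and these size counts may include them. Of the 857 probes higher at 6 h, 733 had also risen against PBS after E. tarda FKC, and of the 1032 lower at 12 h, 838 had fallen. These lists share the E. tarda arrays, and lists of the same sizes from simulated unchanged groups shared 411 and 557 probes. Calls in opposite directions against PBS were found in 1 of these probes at 6 h and in 5 at 12 h, 4 of them higher and 1 lower after E. tarda FKC. The 2 times shared 364 higher and 229 lower probes, where independent lists would share 81.0 and 64.9. No array is common to the groups compared in the 2 lists. The spread of a probe was still estimated once from all arrays, which can raise this overlap and those between times above. CUST_6587_PI426483990 was higher after E. tarda FKC by 4.93 (SE 0.59, limma adjusted p = 1.89e-05) at 6 h and by 4.17 (SE 0.51, limma adjusted p = 1.12e-05) at 12 h. CUST_7579_PI426483990 was lower, at -1.77 (SE 0.44, limma adjusted p = 0.0112) at 6 h and -4.28 (SE 0.38, limma adjusted p = 3.89e-07) at 12 h. Its call at 6 h was lost without E. tarda replicate 2, with a limma adjusted p of 0.06. Fitted on the 2 groups alone, which is the fit within the slide, the counts were 689 at 6 h and 1349 at 12 h. The preparations occupied different rows of the slide. At 6 h all 7 spike-in probes were lower after E. tarda FKC than after S. iniae FKC, by -0.42 to -0.15 with a mean of -0.29 on the log2 scale, and 0 of 7 had an unadjusted limma p under 0.05, the smallest being 0.0739. At 12 h they differed by -0.03 to 0.09, with 0 of 7 and a smallest p of 0.637.

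**Figure D4:**
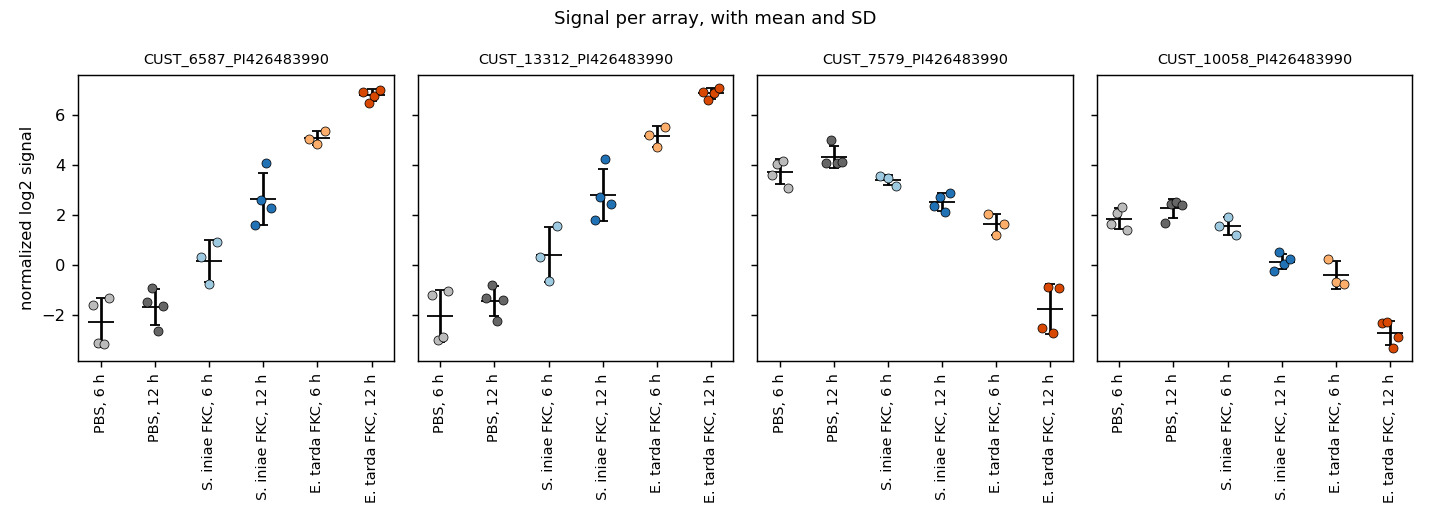
Points give the normalized log2 signal (y axis) of the 4 named probes on each array, by group (x axis), with bars at the mean and SD of 3 or 4 arrays. The left 2 probes reach means of 6.81 and 6.87 after E. tarda FKC at 12 h, and the right 2 reach -1.76 and -2.71.

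The changes against PBS were compared across probes, which are not independent replicates. E. tarda and S. iniae changes had a Pearson correlation of 0.56 at 6 h and 0.70 at 12 h, where unchanged groups sharing the PBS arrays gave 0.43 and 0.50. The covariance was 0.31 at 6 h against a simulated 0.08, and 0.48 at 12 h against 0.08. With 2 PBS arrays for each preparation and none shared the correlation averaged 0.38 at 6 h and 0.55 at 12 h. Both preparations also shared a slide at each time, which splitting the PBS arrays does not remove. At 6 h, 106 of the 115 probes that rose after S. iniae FKC had risen after E. tarda FKC, where lists of these sizes from simulated unchanged groups with the same PBS arrays shared 64.1 and at most 77. Of the 61 that fell, 47 had fallen, against 36.7 and at most 45. With no PBS array shared, a mean of 41.3 probes rose in both at 6 h, of 56.2 that rose after S. iniae FKC, and 10 fell in both, of 29, so the overlap of falling probes was the weakest. Of the probes that rose after S. iniae FKC at 12 h, 509 of 644 had risen after E. tarda FKC, where independent lists would share 100 and such simulated lists shared 329. Of those that fell, 476 of 589 had fallen, against 120 and 352. With no PBS array shared, over 6 splits, a mean of 223 probes rose in both at 12 h, of 331 that rose after S. iniae FKC, and 170 fell in both, of 258, where independent lists would share 37.8 and 37.3. Over the probes that rose after E. tarda FKC at 12 h the median change was 1.18 after E. tarda FKC and 0.46 after S. iniae FKC, on lists chosen for the E. tarda change.

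**Figure D5:**
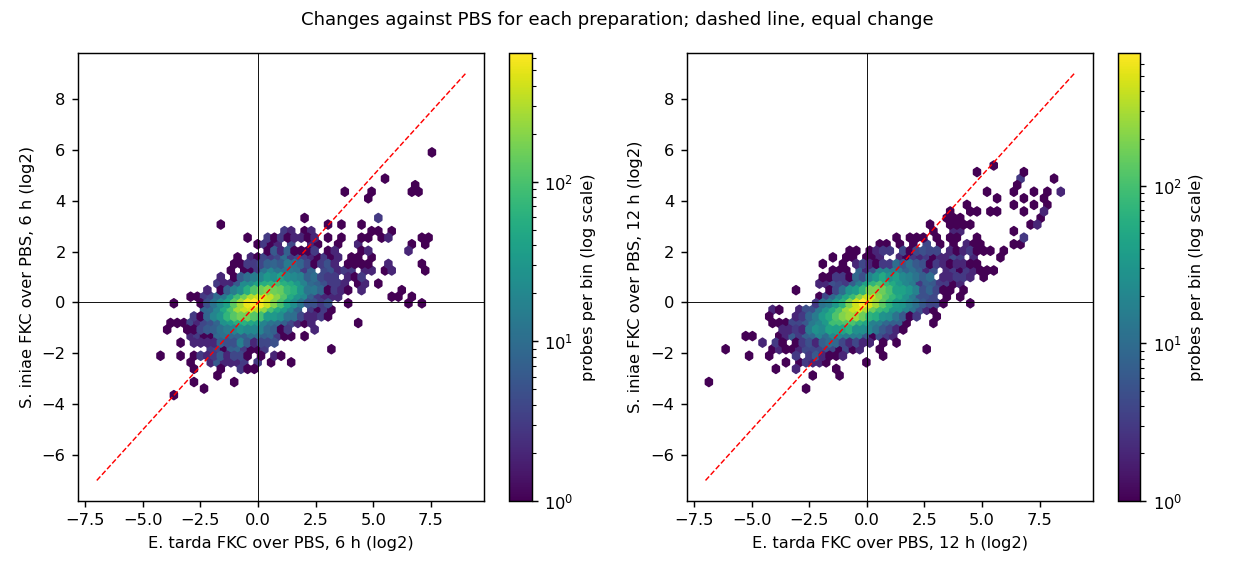
Shading gives the number of tested probes (log colour scale) by their log2 change against PBS after E. tarda FKC (x axis) and after S. iniae FKC (y axis), at 6 h on the left and 12 h on the right. The correlations are 0.56 and 0.70, and the dashed line marks equal change.

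PBS arrays were compared over time on slide 3. At 12 h, 20 probes were higher and 90 lower than at 6 h, and after normexp and quantile normalization 61 were higher and 95 lower. The share of higher calls was thus 18.2% and 39.1%. In 51 of the 110 calls the probe was not well above background on any array of 1 time, and 24 probes were called among those well above background on all arrays. The count was 70 without replicate 4 of 6 h, 65 without replicate 2 or 3 of 12 h, 72 in the fit of the 2 groups alone and 420 with array weights. All 7 spike-in probes were lower at 12 h, by -0.30 to -0.09 on the log2 scale, the direction of most calls, and 0 of 7 had an unadjusted limma p under 0.05, the smallest being 0.173. None of the 4 named probes passed this test.

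The change of effects between the times was tested directly. The difference between E. tarda and S. iniae was called as changed with time in 419 probes, 211 upward and 208 downward. Leaving out 1 array moved this count from 148, without S. iniae replicate 2 of 6 h, to 597, without E. tarda replicate 1 of 6 h, and the fit of the 4 groups alone gave 199. The E. tarda effect against PBS differed between the times in 1245 probes, 500 upward and 745 downward, and the S. iniae effect in 105, 43 upward and 62 downward. Upward and downward give the sign of the 12 h minus the 6 h value, not a stronger or weaker response. The estimates at the 2 times differed in sign in 270 of the 419, 761 of the 1245 and 84 of the 105. Where the sign was the same, the E. tarda effect was larger at 12 h in 366 probes and at 6 h in 118. For the S. iniae effect these were 19 and 2. The count of 1245 was 783 and 747 without E. tarda replicates 2 and 3 of 6 h, 770 without PBS replicate 3 of 12 h, 2037 with normexp and quantile normalization and 2106 with array weights. Both time differences against PBS set FKC arrays of slide 2 against FKC arrays of slide 1, while the PBS arrays of both times share slide 3, so time and slide cannot be told apart in these 2 counts. The spike-in probes moved by -0.27 to 0.63 in the E. tarda difference, where 1 of 7 had an unadjusted limma p under 0.05, and by -0.47 to 0.17 in the S. iniae difference, where 0 of 7 did, the smallest p being 0.112. The difference between the preparations is taken within each slide first, and there all 7 spike-in probes moved upward, by 0.20 to 0.46, with 0 of 7 such p and the smallest 0.133. With arrays scaled to their median the E. tarda effect differed in 719 upward and 468 downward and the S. iniae effect in 59 upward and 25 downward, and with quantile normalization the S. iniae effect differed in 32 upward and 25 downward. For CUST_7579_PI426483990 the E. tarda effect at 12 h minus that at 6 h was -3.995 (SE 0.56, limma adjusted p = 0.000505), a value that holds the difference between slides 2 and 1 as well. It passed the test in all the alternatives run, with adjusted p from 0.000125 to 0.00285. For the same probe the difference between the preparations, taken within each slide first, changed with time by -2.51 (SE 0.58, limma adjusted p = 0.0229). With normexp and quantile normalization that call was lost (limma adjusted p = 0.0536). The count of 105 was 33 with a replicate block, 312 with normexp and quantile normalization and 789 with array weights. It moved by over 1.5 times in 12 of the 15 fits that left out 1 array. It was 18 and 40 without S. iniae replicates 2 and 3 of 6 h, 56 and 48 without S. iniae replicates 2 and 3 of 12 h, 36, 232, 47 and 34 without PBS replicates 1 to 4 of 6 h, and 36, 172, 30 and 43 without PBS replicates 1 to 4 of 12 h.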

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

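The tests of slide difference and those on arrays left out of a selection were chosen after the changes they bear on had been seen, and the other tests before. Of 40 groups of 4 values tested for an array that stands apart, 4 had one, where chance flags about 1 in 20. The residual SD of E. tarda FKC at 12 h replicate 1 was 0.663, the nearest of its group being 0.484, and without it E. tarda FKC against PBS at 12 h called 3753 probes in place of 3976. The spike-in slope of PBS at 6 h replicate 2 was 0.987, the nearest being 1.01. CUST_7579_PI426483990 was at 4.998 on PBS at 12 h replicate 2, the nearest being 4.13, and CUST_10058_PI426483990 was at 1.68 on PBS at 12 h replicate 1, the nearest being 2.41. A difference of effects between the times was found in 419 probes for E. tarda against S. iniae, in 1245 for E. tarda against PBS and in 105 for S. iniae against PBS. The last 2 set slide 2 against slide 1, so time and slide cannot be told apart there.

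Other splits of the same arrays were counted for each result. For E. tarda FKC against PBS only 1 of 35 splits, the real one, called as many probes at each time, with 3111 at 6 h against at most 1330 in the others and 3976 at 12 h against at most 10. For S. iniae FKC it was likewise 1 of 35, with 176 against 72 at 6 h and 1233 against 12 at 12 h. E. tarda against S. iniae at 12 h gave 1 of 35 with 2078 against 29, and PBS over time gave 1 of 35 with 110 against 1. For these 6 results 1 of 35 is the smallest share the splits can give. It lies under the share of 0.05 set beforehand, without adjustment over the results. It does not separate treatment or time from slide or row. At 6 h, E. tarda against S. iniae has 10 splits, too few for a share under 0.05, and called 1553 against at most 2, with 1 split as large. For the time differences 100 regroupings of treatment within each time were drawn, with the real one counted as 1 of the 100. For E. tarda against S. iniae 5 of 100 called as many as 419, the highest 1118, so chance is not excluded. For the E. tarda effect 2 of 100 called as many as 1245, the highest 1750. For the S. iniae effect 2 of 100 called as many as 105, the highest 171. Both lie under the share of 0.05, which says nothing of the slides. Regrouping also takes away the treatment effect at each time, so these shares do not test a time difference alone. For the effects of E. tarda, the regroupings above the real counts swapped 2 or more arrays at 1 time and at most 1 at the other. Such a swap can turn a treatment effect into a time difference, though counts were not compared over all swap patterns. The 1 above the S. iniae count swapped 2 of 3 arrays at 6 h and 4 of 4 at 12 h.

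The calls against PBS lie across slides. If the slide were the whole cause, the other preparation on the same slide would change alike. Over the 3111 E. tarda calls at 6 h the median ratio of the S. iniae to the E. tarda change was 0.279 (0.276 to 0.291 leaving out each S. iniae array), and over the 3976 at 12 h it was 0.419 (0.400 to 0.433). These probes were chosen for the E. tarda change, which by itself lowers the ratio. On arrays left out of the selection it averaged 0.306 at 6 h (0.233 to 0.388 over 18 splits) and 0.414 at 12 h (0.396 to 0.442 over 36 splits), where slide as the whole cause needs about 1. This argues against slide as the whole cause of the E. tarda calls, though not against a part. Over the S. iniae calls the ratio of the E. tarda to the S. iniae change was 1.13 at 6 h and 1.16 at 12 h. On arrays left out of the selection it averaged 1.29 at 6 h (0.924 to 1.75 over 18 splits, with 12 to 120 probes selected). At 12 h it averaged 1.49 there (1.23 to 1.81 over 36 splits). E. tarda arrays thus changed at least as much on average, though not in every split at 6 h. Slide would give 1, or more with an E. tarda effect beside it, and a response common to both preparations would give the same. Noise of the PBS arrays shared by both changes draws such a ratio towards 1. A slide difference may therefore account for the S. iniae calls against PBS, and treatment stays open as well.

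The preparations lie in different rows of their slide. PBS arrays of row 1 minus those of row 2 gave a median ratio to the E. tarda minus S. iniae change of 0.0414 over the 1553 calls at 6 h (0.0173 to 0.0681 leaving out each PBS array) and 0.0335 over the 2078 calls at 12 h (0.0207 to 0.0436). On arrays left out of the selection the ratio was at most 0.101 and 0.119. This argues against a row effect common to the slides as the whole cause. Row and time coincide in the PBS arrays, and a row effect of slide 1 or slide 2 alone stays open. On slide 1 the spike-in probes differed by a mean of -0.29 in the E. tarda row. The spike-in slopes were lower there too, at 0.948 to 0.969 against 0.971 to 0.989 in the S. iniae row. The treatment difference named by the design may account for these calls, as a hypothesis.

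S. iniae FKC gave more calls against PBS at 12 h than at 6 h. With normexp and quantile normalization the counts were closer, 783 at 6 h and 1019 at 12 h, so the size of this difference rests on the processing. With 3 S. iniae arrays at 12 h the lowest count was 806, against 176 at 6 h, which argues against the number of arrays as the whole cause. Over 1149 probes called at 12 h and not at 6 h the median ratio of the E. tarda to the S. iniae change was 1.13, so a difference between the slides may account for it, as may a response common to both preparations. The difference itself was called in 105 probes.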

How the results depend on the processing

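Keeping outlier spots and normexp on median signals were chosen after seeing the data. Apart from leaving out an array, counts stayed within 1.5 times in 11 of 12 for E. tarda FKC against PBS at each time. Normexp with quantile normalization gave 783 probes for S. iniae against PBS at 6 h, 2037 for the time difference of the E. tarda effect and 312 for that of the S. iniae effect, which quantile normalization alone put at 57. No filter gave 286 for S. iniae at 6 h, and the filter for all arrays gave 24 for PBS over time, on fewer probes. Fitting the compared groups alone gave 34 for S. iniae at 6 h, 689 and 1349 for E. tarda against S. iniae at 6 h and 12 h, 72 for PBS over time and 199 for the time difference of E. tarda against S. iniae, on fewer arrays. Array weights gave 597 and 1956 for S. iniae at 6 h and 12 h, 420 for PBS over time, 2106 for the time difference of the E. tarda effect and 789 for that of the S. iniae effect. A 2-fold minimum, stricter by design, gave 1741 and 2291 for E. tarda against PBS, 574 for S. iniae at 12 h, and 955 and 1159 for E. tarda against S. iniae. Otherwise the cause was not tested.

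Replicate numbers equal the column on the slide, and deviations of same-numbered arrays correlated at -0.174 to 0.275. In E. tarda against S. iniae at 6 h all 3 were positive, their mean of 0.14 the highest of 6 matchings, too few for a test, so pairing or a column effect stays open there. With a replicate block the counts were within 1.5 times except the time difference of the S. iniae effect, at 33.

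Leaving out each array gave 1994 to 3417 probes for E. tarda against PBS at 6 h, the lowest without E. tarda replicate 2, and 3373 to 3845 at 12 h. S. iniae against PBS at 6 h ranged from 51 to 224, with 51 and 73 without S. iniae replicates 2 and 3, 88 without PBS replicate 3, and also moved by over 1.5 times without PBS replicate 1. At 12 h it ranged from 724 to 1372, with 806 without S. iniae replicate 2, and 724 and 741 without PBS replicates 3 and 4. E. tarda against S. iniae ranged from 881 to 2015 at 6 h, with 881 without E. tarda replicate 2, and 957 and 932 without S. iniae replicates 2 and 3, and from 1644 to 1820 at 12 h. PBS over time ranged from 65 to 121, with 70 without replicate 4 of 6 h and 65 without replicate 2 or 3 of 12 h. The time difference of E. tarda against S. iniae ranged from 148 to 597, with 224 without E. tarda replicate 2 of 6 h, 148 and 197 without S. iniae replicates 2 and 3 of 6 h, and 279 without S. iniae replicate 4 of 12 h. That of the E. tarda effect ranged from 747 to 1600, with 783 and 747 without E. tarda replicates 2 and 3 of 6 h and 770 without PBS replicate 3 of 12 h. That of the S. iniae effect ranged from 18 to 232, without S. iniae replicate 2 and PBS replicate 2 of 6 h, and moved by over 1.5 times in 12 of 15 cases.

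For the 4 named probes, 474 of 507 alternatives of their 26 called comparisons kept the direction and the call, 33 lost the call and 0 reversed. The gene list tests were not run, since no name matched. A slide block could not be fitted. The authors' values gave no value for PBS over time. Dim signal limits the folds of dim probes.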

Other observations

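Probes named by a GenBank entry, 320 of those tested, were compared with 10731 contig probes by how often they were called, using 10000 contig sets matched on mean signal. At 12 h, 46.2% of them were called for E. tarda FKC against PBS, 77 higher and 71 lower, where matched sets gave 30 to 40% (adjusted one-sided permutation p = 7e-04 over 7 comparisons, from a raw p of 1e-04, the smallest these sets can give). At 6 h, 30.3% were called, within the 23.4 to 32.8% of matched sets (adjusted permutation p = 0.22), so no excess was shown at 6 h. Matching on signal hardly moved the contig share, with a median of 35% in matched sets against 35.6% in all contig probes at 12 h, which argues against brighter signal as the source of the share at 12 h. For S. iniae FKC against PBS 4.69% were called at 6 h (adjusted permutation p = 0.0019) and 16.2% at 12 h (0.0024). For E. tarda against S. iniae 15.9% were called at 6 h (0.13) and 26.9% at 12 h (0.0018), and for PBS over time 0.625% (0.65). Probes are not independent, which makes these p-values too small where probes move together.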
